A study of Homo sapiens with 6 samples.

How the data were processed

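RNA of 6 samples of the human colorectal carcinoma lines LoVo and DLD-1, transduced with the empty retroviral vector MSCV-PIG or with the same vector carrying LIN28B, was measured on 1 Affymetrix gene-level array each. Per the labels' protocols, cells were grown in DMEM with serum, RNA was isolated with a mirVana kit, and biotinylated cRNA was prepared from 6 µg of total RNA. Groups were taken from the labels: 1 array of DLD-1 vector, 1 of DLD-1 LIN28B, 2 of LoVo vector and 2 of LoVo LIN28B. The labels number only the second LoVo pair. The unnumbered LoVo arrays were numbered 1 here, and names such as LoVo vector 1 follow this numbering. The labels do not say that arrays of the same number share a batch.

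The deposited series table holds one log2 value per probe set and array, as its values show (between 2.07 and 13.97, with array medians within 0.09 of each other). The authors' summarization, background correction, normalization method and software are not given in the sources used here, so their effect on these log2 values stays unknown. The near-equal distributions mean that a shift common to most genes of an array would not be visible. The values were used as deposited.

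Probe sets were named through the platform's annotation table. Of the probe sets, 19310 had 1 gene symbol, 1752 had several and 7864 had none; the latter kinds were left unnamed. Symbols were updated by Entrez identifier through the RefSeq gene table of GRCh38.p14, which 19279 of the single-symbol probe sets matched; that table served only for names and for the order of neighbouring genes, and the authors' own build is not given in the sources used here. For a gene with more than 1 single-symbol probe set (685 genes), the one of highest mean over the 6 arrays was used, and 18377 genes were tested. HMGA2, named in advance, was not analysed here, as no probe set carried its symbol alone.

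Tests were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fixed before the data were examined were the fits of LIN28B against vector in LoVo (4 arrays, 2 residual degrees of freedom), over both lines with the line as a covariate (6 arrays, 3 residual degrees of freedom), the interaction of line and LIN28B (4 group means), LoVo against DLD-1 with the label as a covariate, the untested DLD-1 difference and the correlations between lines. So were 24 gene lists and the rule for named genes. The rule names LIN28B, LGR5, PROM1, HMGA2, IGF2BP1, IGF2BP3, MYC and CDH1 whatever their values; 1 further item of the rule is not reported here. It adds the 10 largest differences each way among genes past the threshold whose groups do not overlap and whose higher group lies above the median of all probe sets (5.97), with free places filled by size, 8 each way in DLD-1, and up to 4 members of each list by size. That last part was fixed for the LoVo comparison; members named in other comparisons were ordered by their size there. Genes of the Y chromosome and XIST were left out of the named genes. Lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one. With the estimated one, camera also judges each list on the fit's residual degrees of freedom. With only 1 to 3 of these, hardly any list could pass. A failure there does not separate the correlation of genes from the small number of arrays. In DLD-1, a list's median was placed among 10000 random lists of the same size matched on mean expression.

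LIN28B ran against the labels in the second LoVo pair. Labelled groups were kept in all fixed fits, and a fit of the other 4 arrays (line and label as terms, 1 residual degree of freedom) was added after seeing the data, with its gene list tests and the matching line comparison. The named genes of the added fit follow the same rule. Also chosen after seeing the data were the list of abundant hepatocyte transcripts, the slope between LoVo pairs and the test of neighbouring genes. For the latter, genes with a mean log2 value above 7 were ordered along the chromosomes, cut into windows of 40 genes (at least 20), and the covariance of window medians between pairs was set against 1000 shuffles of gene positions; these window settings were set during a first look and no others were tried.

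The fits were tested on simulated data with 200 changed genes, built from the real genes' means per line and the prior spread of the fit of 4 arrays. At a true change of 1 log2, 91.0% of changed genes were recovered in the LoVo fit, 94.0% in the fit of both lines and 86.6% in the fit of 4 arrays; at 0.5 log2 the shares were 4.48%, 7.46% and 1.49%, and at 2 log2 all were recovered. False calls were 9 of 139, 2 of 136 and 13 of 138 calls. These shares hold for arrays that follow their labels. The real fits of LoVo and of both lines held the second LoVo pair. Their priors had 2.11 and 2.29 degrees of freedom, in place of the simulated 7.43. The simulated shares therefore do not describe those fits, and their counts of 0 called genes are not evidence against changes of 1 log2. Alternatives were quantile normalization, median centring, a filter at the 40th percentile of mean level (5.29), every probe set on its own, the mean of a gene's probe sets, eBayes with trend and robust options, the replicate block (and, after seeing the data, a crossed block), each array left out in turn, and other sizes and correlations where they apply. Figures were drawn with matplotlib 3.10.9.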

Results

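Gene expression was measured in LoVo and DLD-1, established human colorectal carcinoma lines, transduced with a retroviral vector that was either empty or carried LIN28B, an RNA-binding protein that blocks maturation of the let-7 microRNAs. Each of the 6 samples was hybridised to 1 Affymetrix gene-level array. DLD-1 had 1 array labelled vector and 1 labelled LIN28B, and LoVo had 2 arrays of each label. The deposited table had array medians between 5.93 and 6.01 on the log2 scale, and 18377 genes entered the tests. The number of arrays limits the precision. The labels call the second LoVo pair additional lines but do not say that arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

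LIN28B itself was examined first in every array, because its level checks the labels. In DLD-1 its log2 signal was 3.68 in the vector array and 7.59 in the LIN28B array. In LoVo it was 3.82 in the array labelled vector 1 and 7.83 in the array labelled LIN28B 1. The second LoVo pair ran against its labels: the signal was 8.04 in the array labelled LoVo vector 2 and 3.60 in the array labelled LoVo LIN28B 2. PROM1 (CD133) and LGR5, markers of intestinal stem cells, and IGF2BP1, an RNA-binding protein encoded by a let-7 target, followed the LIN28B signal and not the label. PROM1 measured 9.31 in the array labelled LoVo vector 2 and 4.65 in the array labelled LoVo LIN28B 2. Over all probe sets, the array labelled LoVo LIN28B 2 correlated best with the array labelled LoVo vector 1 (Pearson r = 0.996), and the array labelled LoVo vector 2 with the array labelled LoVo LIN28B 1 (r = 0.994). The main comparisons below kept every array in its labelled group. A further fit left out the second LoVo pair and was added after the values had been seen.

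**Figure D1:**
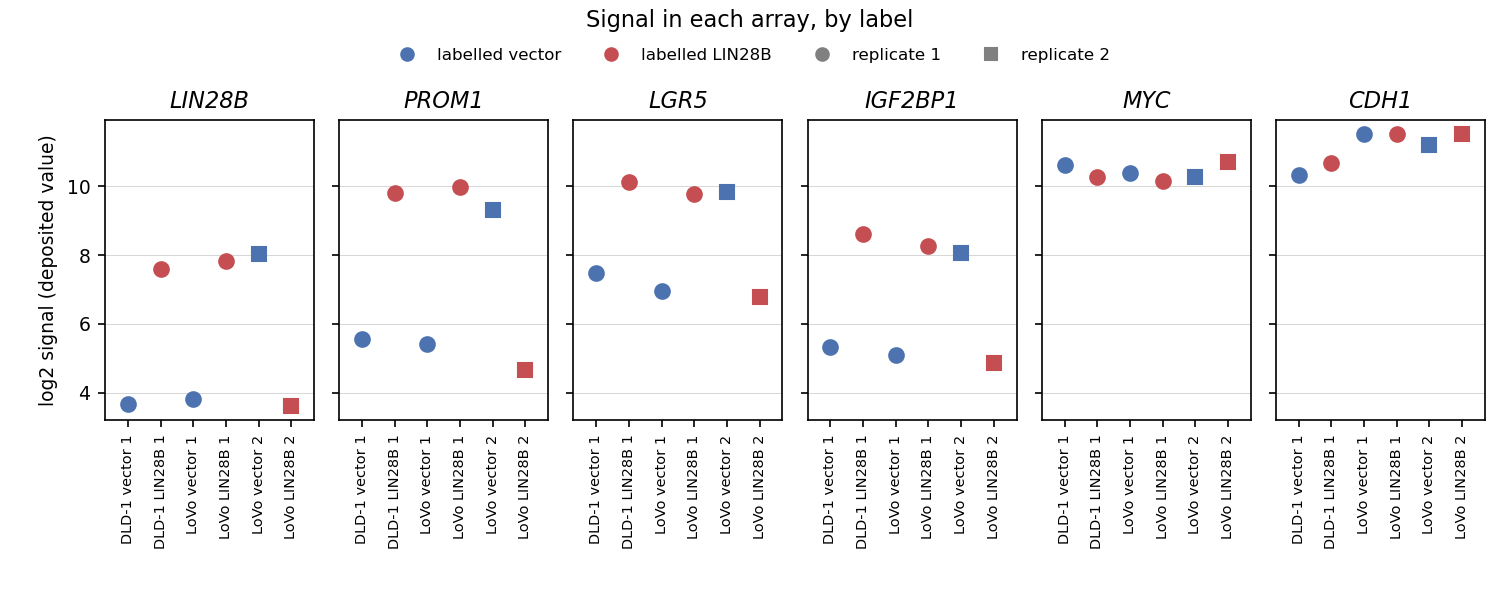
Log2 signal of 6 genes in each of the 6 arrays; colour gives the label (vector or LIN28B) and shape the replicate number, 1 point per array. LIN28B, PROM1, LGR5 and IGF2BP1 are high in the array labelled LoVo vector 2 and low in the array labelled LoVo LIN28B 2, for example 8.04 and 3.60 for LIN28B, whereas MYC and CDH1 differ little within each line.

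The series was built around the question of which transcripts change in LoVo cells that express LIN28B constitutively. With the 4 LoVo arrays in their labelled groups (n = 2 per group), no gene passed the test. LIN28B measured −0.21 ± 2.09 (log2 difference ± SE) in the arrays labelled LIN28B relative to those labelled vector, PROM1 −0.05 ± 2.30, LGR5 −0.12 ± 1.45 and IGF2BP1 −0.01 ± 1.59, since the LoVo pairs had opposite signs for each of these genes. IGF2BP3 differed by 0.25 ± 0.28, MYC by 0.11 ± 0.23 and CDH1, the epithelial cadherin, by 0.16 ± 0.17. Of the genes whose labelled groups did not overlap, the largest positive values were those of SESN3, a sestrin of the stress response, at 0.87 ± 0.34, SLC16A4 at 0.82 ± 0.35, ACBD7 at 0.80 ± 0.17, ZNF487 at 0.78 ± 0.27 and complement factor B (CFB) at 0.70 ± 0.22. The largest negative values were those of ACR at −0.70 ± 0.18, TEX52 at −0.59 ± 0.14, the heparin-binding growth factor midkine (MDK) at −0.59 ± 0.31, MIR134 at −0.58 ± 0.14 and ULBP2, a ligand of the NKG2D receptor, at −0.53 ± 0.16. In limma, 0 genes were higher and 0 lower at an adjusted p of 0.05, the adjusted p of each gene named here was 0.9999, and 82 genes had an unadjusted p under 0.05 where chance alone gives 918.85.

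None of the 24 gene lists fixed before the data were examined had a called member in LoVo as labelled, over all genes or adjusted over the list alone. With limma's camera test and its preset inter-gene correlation, oxidative phosphorylation genes lay lower (78 genes, median −0.11, adjusted p = 0.000277), while p53 targets (21 genes, median 0.11, adjusted p = 0.00314) and interferon response genes (28 genes, median 0.15, adjusted p = 0.0194) lay higher. With a correlation estimated from the 4 arrays, adjusted p = 0.974 for each of these lists. That version had 2 residual degrees of freedom and could hardly pass any list. Examples were ATP5MC1 at −0.36 ± 0.16, NDUFB3 at −0.32 ± 0.18, the p53-regulated death receptor TNFRSF10B at 0.41 ± 0.16 and IFIT3 at 0.37 ± 0.16. Medians in the first and second LoVo pairs were −0.07 and −0.16 for oxidative phosphorylation, 0.21 and 0.08 for p53 targets, and 0.03 and 0.25 for interferon response. Each labelled group held an array of high and an array of low LIN28B signal, so these list values do not measure a response to LIN28B.

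Over both lines as labelled (3 arrays per label, with the line as a covariate), no gene passed the test either. LIN28B differed by 1.16 ± 1.72, PROM1 by 1.38 ± 1.88, LGR5 by 0.80 ± 1.19 and IGF2BP1 by 1.09 ± 1.33. IGF2BP3 differed by 0.36 ± 0.21, CDH1 by 0.22 ± 0.13 and MYC by −0.05 ± 0.19. The genes with the largest values among those whose labelled groups were apart within each line were SESN3 at 1.22 ± 0.33, IFRD1 at 0.66 ± 0.23, CFB at 0.62 ± 0.17 and PAQR8 at 0.60 ± 0.12. On the other side were ACR at −0.59 ± 0.15, cyclin E2 (CCNE2) at −0.57 ± 0.20, BHLHA9 at −0.50 ± 0.12 and GMPPB, an enzyme of GDP-mannose synthesis, at −0.47 ± 0.11. SESN3 was higher in the array labelled LIN28B in 3 of 3 pairs, by 1.93 in DLD-1 and by 1.52 and 0.21 in the LoVo pairs. In limma, 0 genes were higher and 0 lower, with an adjusted p of 0.9999 for these genes, and 175 genes had an unadjusted p under 0.05.

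Of the gene lists over both lines as labelled, camera with the preset correlation placed 5 higher and 2 lower, with no called member in any list. The higher lists were interferon response (median 0.14, adjusted p = 0.000518), epithelial adhesion (median 0.10, adjusted p = 0.00118), let-7 targets (median 0.11, adjusted p = 0.00822), absorptive colonocyte differentiation (median 0.11, adjusted p = 0.0294) and p53 targets (median 0.07, adjusted p = 0.0294). The lower ones were proliferation (median −0.15, adjusted p = 0.00118) and oxidative phosphorylation (median −0.07, adjusted p = 0.0137). Medians in the DLD-1, first and second LoVo pairs disagreed for let-7 targets (0.36, 0.42 and −0.36) and colonocyte differentiation (0.34, 0.13 and −0.20). They also disagreed for proliferation (−0.32, 0.25 and −0.58) and p53 targets (−0.05, 0.21 and 0.08). The remaining lists kept the same sign in every pair. None of the 7 lists held with an estimated correlation, where adjusted p = 0.599 for epithelial adhesion and adjusted p = 0.833 for each of the others. That version had 3 residual degrees of freedom and could hardly pass any list.

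Without the second LoVo pair, arrays labelled LIN28B and vector differed at many genes (n = 2 per label, 1 pair per line). FN1, which encodes fibronectin, showed the largest difference, at 4.29 in the vector arrays and 11.54 in the LIN28B arrays on the log2 scale, a difference of 7.25 ± 0.16 (SE). It was followed by the trypsin inhibitor SPINK1 (5.45 ± 0.19), the YAP-responsive gene ANKRD1 (5.33 ± 0.14), the receptor tyrosine kinase KIT (5.05 ± 0.16), GASK1B (4.95 ± 0.15), the actin-bundling protein LCP1 (4.92 ± 0.17), the secreted Wnt inhibitor DKK1 (4.89 ± 0.15), the proteoglycan GPC3 (4.65 ± 0.19), HAVCR1 (4.56 ± 0.25) and TTR, the plasma carrier transthyretin (4.54 ± 0.18). The largest negative difference was that of the growth factor pleiotrophin (PTN, −4.33 ± 0.21), followed by the SP3 pseudogene SP3P (−3.85 ± 0.16), ODAM (−3.31 ± 0.15), APCDD1, another Wnt inhibitor (−3.11 ± 0.21), and FGF20 (−2.80 ± 0.31). ZNF738, the pyrimidine-degrading enzyme gene DPYD, RAB38, RPS6KA6 and MKX followed, between −2.78 and −2.20. Among the genes named in advance, LIN28B differed by 3.96 ± 0.15, PROM1 by 4.40 ± 0.16, LGR5 by 2.73 ± 0.15, IGF2BP1 by 3.23 ± 0.15 and IGF2BP3 by 0.67 ± 0.15. MYC (−0.30 ± 0.15, adjusted p = 0.286) and CDH1 (0.16 ± 0.16, adjusted p = 0.651) did not pass.

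In this fit limma called 1067 genes higher and 781 lower in the arrays labelled LIN28B, and 4090 genes had an unadjusted p under 0.05. The adjusted p was 3.6e-07 for FN1, 2.7e-06 for LIN28B and 0.0107 for MKX, the weakest of the 20 genes with the largest differences. In the second LoVo pair as labelled, 1824 of these 1848 genes (98.7%) had the opposite sign, with a median size ratio of −0.97 to the fit without it. FN1, for example, differed by −7.07 there, PROM1 by −4.66 and PTN by 4.70. The fit had 1 residual degree of freedom, so most of its spread came from limma's prior of 7.43 degrees of freedom. A gene with opposite signs in the DLD-1 pair and the first LoVo pair could hardly be called in it, and the calls rest on leaving out the pair whose LIN28B signal ran against its labels.

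**Figure D2:**
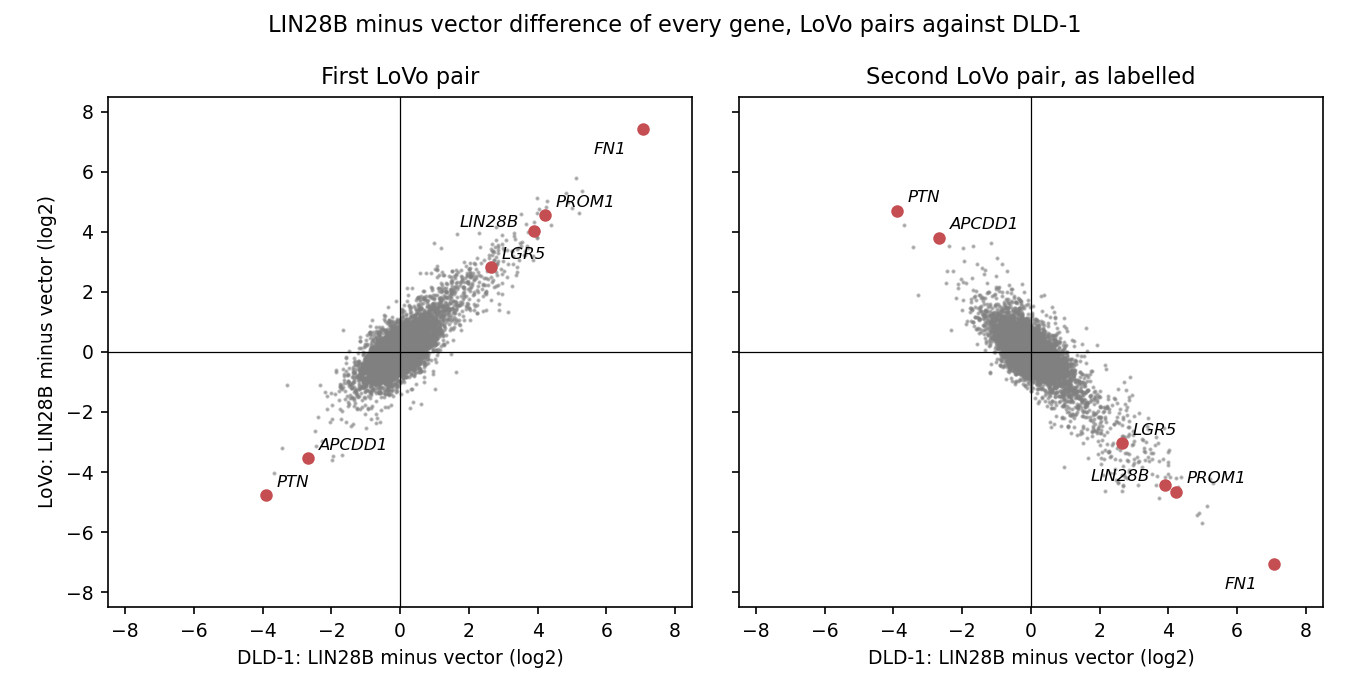
Log2 difference, LIN28B minus vector as labelled, of each of the 18377 genes in DLD-1 (horizontal) against the first LoVo pair (left) and the second LoVo pair (right); 6 named genes are in red. The cloud runs upward for the first pair (r = 0.75 across genes) and downward for the second (r = −0.76), with FN1 at 7.43 and −7.07.

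The gene groups moved as follows without the second LoVo pair, where 1067 genes were higher and 781 lower of all 18377. Of 32 measured let-7 targets, 10 were higher and 0 lower (15 and 0 adjusted over the list alone), among them IGF2BP1, cyclin D2 (CCND2, 2.68 ± 0.15), thrombospondin 1 (THBS1, 2.54 ± 0.18) and MYCN (1.38 ± 0.15). Of 25 absorptive colonocyte genes, 7 were higher and 0 lower (10 and 0 adjusted over the list alone), led by the brush-border peptidase DPP4 (3.46 ± 0.20), CEACAM6 (2.35 ± 0.15) and CEACAM5, the carcinoembryonic antigen (2.32 ± 0.14). Of 16 goblet and secretory genes, 6 were higher and 0 lower, the same counts as adjusted over the list alone, including REG4 (2.90 ± 0.16), AGR2 (2.72 ± 0.23) and the transmembrane mucin MUC13 (2.14 ± 0.15). Of 18 mesenchymal markers, 6 were higher and 0 lower (7 and 0 adjusted over the list alone): besides FN1 these included TGFBI (3.31 ± 0.15), CALD1 (1.71 ± 0.16) and S100A4 (1.64 ± 0.14). The other 12 were not called, among them VIM (0.04 ± 0.17), CDH2 (0.24 ± 0.15), ZEB1 (−0.20 ± 0.15) and TWIST1 (−0.12 ± 0.14), and the list's median was 0.16 with a mean of 0.93. Smaller shares rose in the lists of epithelial adhesion (5 of 21, led by CLDN1 at 2.70 ± 0.15; 5 higher and 1 lower adjusted over the list alone), invasion and matrix proteases (6 higher and 1 lower of 24; 8 and 1 adjusted over the list alone), replication histones (10 higher and 1 lower of 55; 10 and 2 adjusted over the list alone) and cholesterol synthesis (2 of 17; 3 adjusted over the list alone). The histone medians had opposite signs in the pairs of this fit, −0.10 in DLD-1 and 0.17 in the first LoVo pair. Of 15 fibroblast markers, a check for other cell types, 2 were higher, FBLN1 (2.04 ± 0.22) and PDGFRA (1.32 ± 0.20), and 0 lower (3 and 0 adjusted over the list alone). Camera with the preset correlation placed these 9 lists higher, from adjusted p = 1.4e-07 for let-7 targets to adjusted p = 0.0266 for epithelial adhesion, histones, cholesterol synthesis and fibroblast markers. With an estimated correlation, adjusted p = 0.738 for each of them.

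The other 15 lists did not pass camera in this fit, though single members were called. With 1067 genes higher and 781 lower of 18377 in this fit, a few called members do not show a change of their list. Intestinal stem cell markers had 5 members higher and 2 lower of 21 (6 and 3 adjusted over the list alone), with ALDH1A1 (3.03 ± 0.18) and CD24 (2.19 ± 0.22) beside PROM1 and LGR5 on the higher side; the list's median was −0.06 and its mean 0.50. Wnt targets had 2 higher and 6 lower of 23 (5 and 9 adjusted over the list alone): DKK1 and LGR5 were higher, while APCDD1 and the Wnt deacylase NOTUM (−1.94 ± 0.23) were lower. Interferon response genes had 6 higher and 3 lower of 28 (7 and 4), with BST2 at 2.47 ± 0.14 and IFITM1 at −1.12 ± 0.14. NF-kB and inflammatory genes had 2 higher and 2 lower of 18 (4 and 2), among them lipocalin 2 (LCN2, −2.19 ± 0.15) and ICAM1 (−1.82 ± 0.15). Hypoxia genes had 4 higher and 1 lower of 18 (4 and 2), glycolysis 3 and 0 of 19 (3 and 0), with the glucose transporter SLC2A3 at 2.44 ± 0.23, and p53 targets 3 and 0 of 21 (4 and 0). Ribosomal protein genes had 3 higher and 1 lower of 63 (3 and 1), the paralogue RPL39L standing apart at 3.03 ± 0.15. Proliferation genes had 0 higher and 1 lower of 30 (0 and 1), the latter being CCNE2 (−0.73 ± 0.15), and oxidative phosphorylation 0 and 1 of 78 (0 and 0). One member was higher and 1 lower among enteroendocrine markers, stress genes of the unfolded protein and amino acid responses, and insulin and IGF signalling genes, of 15, 23 and 21 measured (1 and 1 in each). Leukocyte markers had 1 higher of 16, LCP1, and 0 lower (1 and 1), and endothelial markers had 0 higher and 1 lower of 12 (0 and 1), the latter being TEK at −0.61 ± 0.15. The pairs in the last brackets of each list are the counts adjusted over the list alone.

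**Figure D3:**
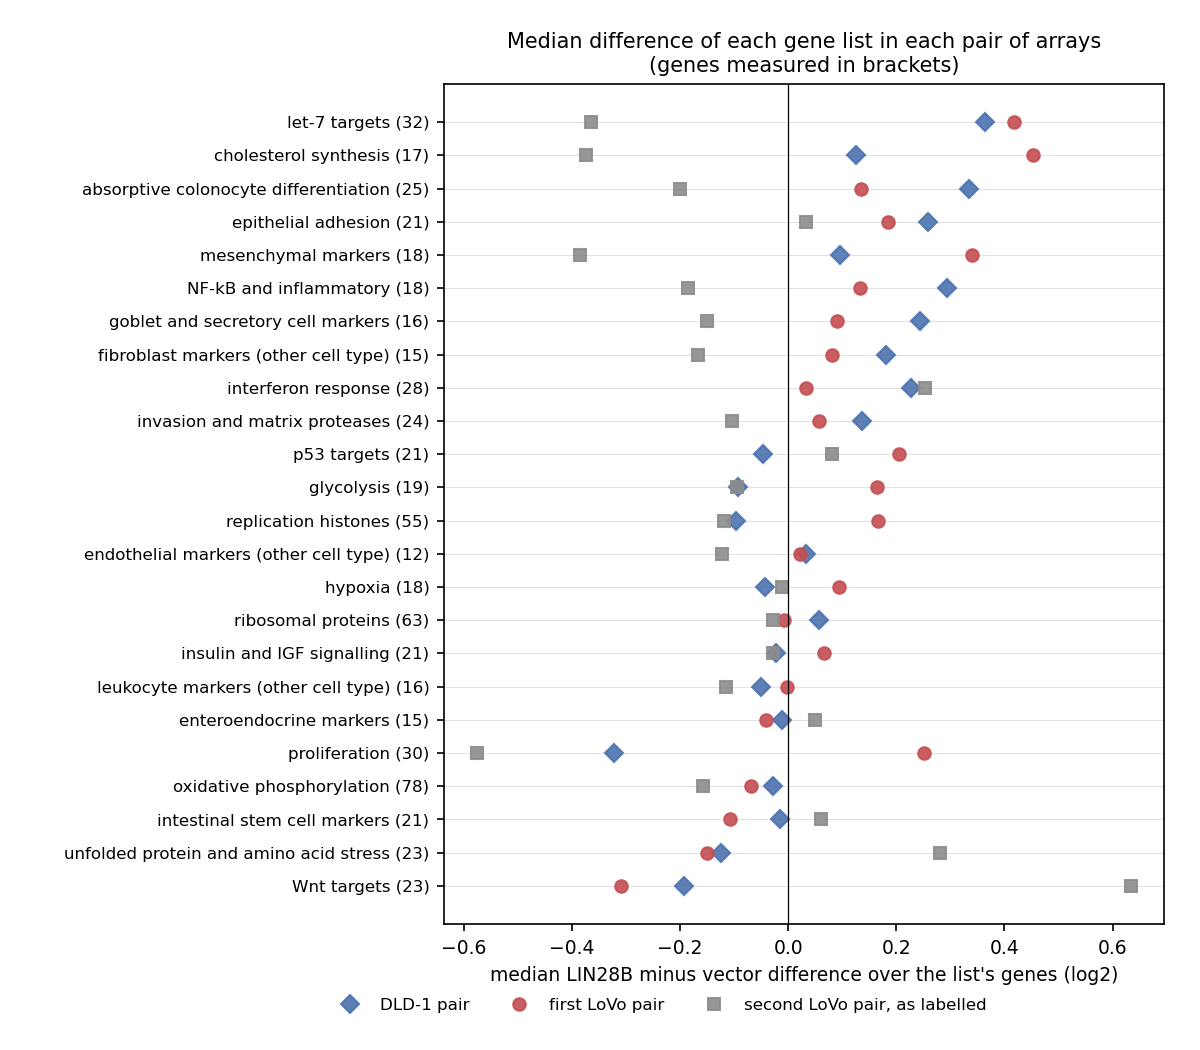
Median LIN28B minus vector difference (log2) of each of the 24 gene lists in the DLD-1 pair, the first LoVo pair and the second LoVo pair as labelled, with the number of genes measured in brackets; 1 point per list and pair. For let-7 targets the medians are 0.36 in DLD-1, 0.42 in the first LoVo pair and −0.36 in the second, and for Wnt targets −0.19, −0.31 and 0.63.

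In DLD-1 the comparison rested on 1 array per label and has no replicate check. The LIN28B array exceeded the vector array by over 1 log2 at 533 genes and lay below it by over 1 log2 at 252. The largest positive differences were FN1 (7.07), ANKRD1 (5.30), LCP1 (5.20), SPINK1 (5.11), DKK1 (4.99), GASK1B (4.89), KIT (4.83) and PEG10, an imprinted retrotransposon-derived gene (4.38). The largest negative ones were PTN (−3.90), SP3P (−3.68), ODAM (−3.44), MKX (−3.30), APCDD1 (−2.67), ZNF738 (−2.44), RPS6KA6 (−2.38) and the chemokine gene CCL2 (−2.34). The median of the let-7 targets, 0.36, lay above all of 10000 random lists of the same size matched on mean expression, as did those of colonocyte differentiation (0.34), epithelial adhesion (0.26), interferon response (0.23) and NF-kB genes (0.29) in these arrays. In the first LoVo pair the percentiles were 100 for let-7 targets, 99.36 for colonocyte differentiation, 99.05 for epithelial adhesion, 97.35 for NF-kB genes and 89.34 for interferon response. Such random lists ignore the correlation between a list's genes. The proliferation list had a median of −0.32, at the 0.01 percentile of such lists, whereas in the first LoVo pair its median was 0.25, at the 99.97 percentile. Of the 785 genes that differed by over 1 log2 in DLD-1, 768 had the same sign in the first LoVo pair and 769 the opposite sign in the second LoVo pair as labelled.

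The difference between the lines in their LIN28B effect was tested with the labelled groups. LIN28B gave an interaction of −4.12 ± 3.61, LoVo minus DLD-1, PROM1 −4.28 ± 3.99, LGR5 −2.76 ± 2.52 and IGF2BP1 −3.29 ± 2.75. IGF2BP3 gave −0.34 ± 0.48, MYC 0.47 ± 0.40 and CDH1 −0.18 ± 0.29. In limma 0 genes passed in either direction, the adjusted p of these genes was 0.989, and 317 genes had an unadjusted p under 0.05. The spread came from the LoVo arrays alone, whose second pair ran against its labels.

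Several of the genes with the largest positive LoVo minus DLD-1 values, DDIT4, CHAC1 and SLC7A11, belong to the amino acid stress response. DDIT4, an inhibitor of mTORC1, was higher in LoVo by 3.71 ± 0.15 and was the only gene to pass the test with all 6 arrays as labelled (limma adjusted p = 0.0218). CHAC1, a glutathione-degrading enzyme, measured 3.49 ± 0.32 (adjusted p = 0.0609), the cystine transporter SLC7A11 2.73 ± 0.31 (adjusted p = 0.0671) and asparagine synthetase (ASNS) 2.05 ± 0.17 (adjusted p = 0.0580). TCP11L2 (3.11 ± 0.24), ULBP1 (3.06 ± 0.39), SLC16A4 (2.74 ± 0.37), NUPR1 (2.42 ± 0.53), PCK2 (2.28 ± 0.17), SELENBP1 (2.28 ± 0.66) and YPEL5 (2.23 ± 0.23) also lay higher in LoVo without passing. Of the 10 genes with the largest negative values, between TMEM51-AS1 at −2.00 ± 0.26 and SNORD14C at −1.44 ± 0.20, 3 were small nucleolar RNAs (SNORD14E, SNORD30 and SNORD14C) and 1 was the acetyl-CoA acetyltransferase gene ACAT2 (−1.49 ± 0.48). In the list of unfolded protein and amino acid stress genes, 13 of 23 were higher and 1 lower adjusted over the list alone, against 1 and 0 over all genes. Its median was 0.99 (camera adjusted p = 1.9e-07 with the preset correlation; adjusted p = 0.476 with an estimated correlation).

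In all, 11 lists passed camera between the lines with the preset correlation and none with an estimated one, which had 3 residual degrees of freedom. Proliferation genes had a median of −0.62 (adjusted p = 7.4e-08; adjusted p = 0.476 with an estimated correlation). Epithelial adhesion had one of 0.43 (adjusted p = 7.2e-05; adjusted p = 0.297 with an estimated correlation) and hypoxia genes one of 0.39 (adjusted p = 0.00183; adjusted p = 0.297 with an estimated correlation). Invasion genes (median 0.36, adjusted p = 0.00719), interferon response (0.35, adjusted p = 0.0158), insulin and IGF signalling (0.21, adjusted p = 0.0113) and Wnt targets (0.33, adjusted p = 0.0332) also lay higher in LoVo, and oxidative phosphorylation (−0.12, adjusted p = 0.00143), cholesterol synthesis (−0.36, adjusted p = 0.0315) and replication histones (−0.15, adjusted p = 0.0386) lower. With an estimated correlation, adjusted p = 0.297 for invasion and for insulin and IGF signalling, 0.476 for interferon response, Wnt targets and oxidative phosphorylation, 0.574 for cholesterol synthesis and 0.879 for histones. All 6 arrays together left 1 gene past the threshold, 4342 genes with an unadjusted p under 0.05, and no gene past it when any 1 array other than the array labelled LoVo vector 2 was left out. Without the second LoVo pair, limma called 2372 genes higher and 990 lower in LoVo, DDIT4 by 3.78 and CHAC1 by 3.56. In the same 4 arrays the largest differences lay between labels, with 69 genes over 3 log2 against 4 between lines. The median size over all genes was 0.25 between lines and 0.17 between labels. Over all probe sets, the LoVo vector 1 array correlated slightly better with the DLD-1 vector array than with the LoVo LIN28B 1 array. The DLD-1 LIN28B and LoVo LIN28B 1 arrays went the other way, each correlating better with its own line's vector array. These correlations therefore do not clearly separate the lines, and no reference profile was used to check the line labels. The differences between lines describe the arrays as labelled.

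**Figure D4:**
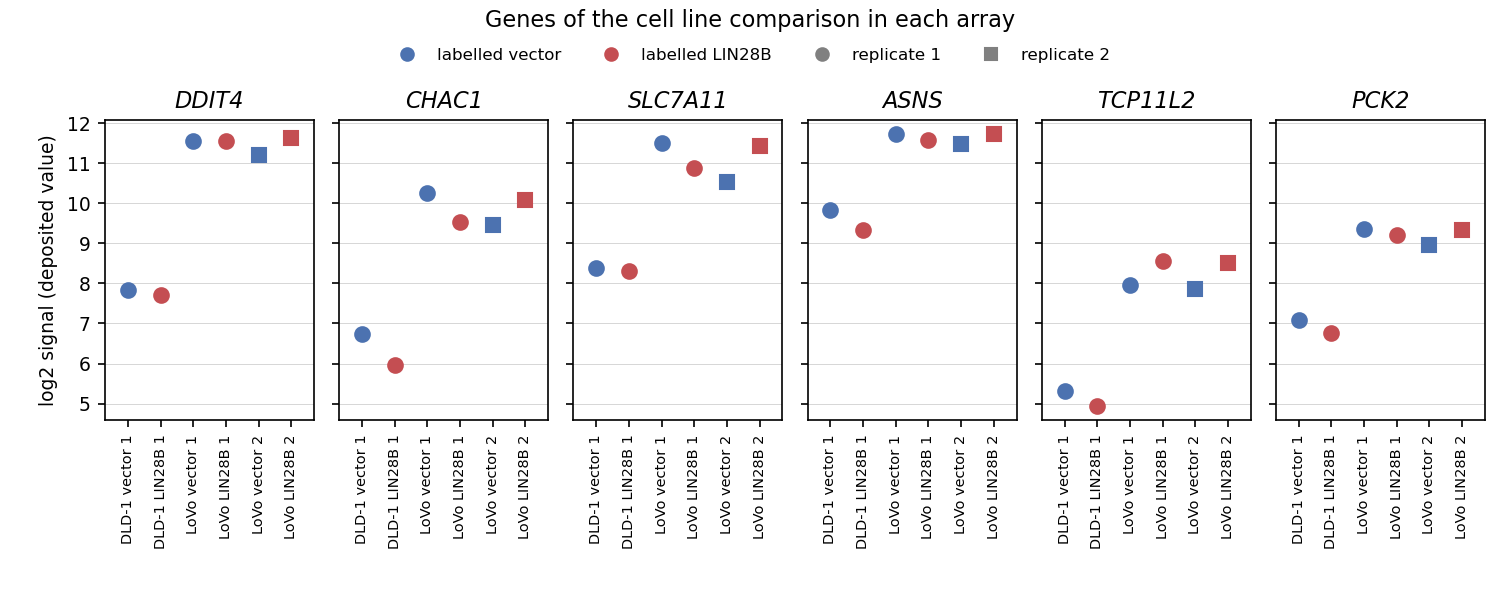
Log2 signal of 6 genes with large LoVo minus DLD-1 differences in each of the 6 arrays; colour gives the label and shape the replicate number, 1 point per array. All 4 LoVo arrays lie above both DLD-1 arrays for each gene, for example by 3.71 on average for DDIT4.

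Agreement of the LIN28B differences between lines depended on the LoVo pair. Across 18377 genes, which are not independent replicates, the DLD-1 differences had Pearson r = −0.04 and Spearman rho = −0.07 with the mean of the LoVo pairs as labelled, and 48.5% of genes shared a sign. With the first LoVo pair r was 0.75, rho 0.47 and the share 64.3%; with the second it was −0.76, −0.52 and 35.1%. The first and the second LoVo pair, which share no array, had r = −0.85 and rho = −0.61 between them. Crossed pairs, each LIN28B-labelled array against the vector-labelled array of the other number, had r = −0.10. Over the 785 genes that differed by more than 1 log2 in DLD-1, r was 0.93 with the first LoVo pair and −0.92 with the second. No gene was called in LoVo as labelled, so the share of called genes with the same sign in DLD-1 has no value.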

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

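Of the tests in this part, the one of gene density and the count over other splits of the arrays were fixed before their results were seen; the slope and its bound, the arrays' best matches, the share of opposite signs, the hepatocyte genes, the windows and the count of shared genes were chosen only after the result was seen.

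Among the 9616 probe sets with no symbol or with several, which no test of genes or lists in the report used, 24 differed between labels without the second LoVo pair, 22 higher and 2 lower in the arrays labelled LIN28B, and all 24 had the opposite sign in that pair as labelled. This count cannot be set against that of the named genes. A probe set at 4.65 ± 0.13 had a limma adjusted p of 0.00504 here, whereas TTR at 4.54 ± 0.18 had 4e-06 in the fit of genes.

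The second LoVo pair ran against its labels over the whole profile. The tables argue against a partial mixing of the RNA, since the upper bound of the slope's bootstrap interval was −0.990, and against one wrong label alone, since 0 of the 2 arrays correlated best with the first array of their own label. An exchange of the arrays labelled LoVo vector 2 and LoVo LIN28B 2 is a candidate explanation: over 785 genes chosen in DLD-1, the slope of the second pair on the first was −1.01 (95% bootstrap interval −1.03 to −0.99, across genes, which are not independent). A true difference between these cultures that goes against their labels cannot be told apart from an exchange by the opposite signs in 98.7% of the genes called without that pair, because both predict them. LIN28B itself read 8.04 in the array labelled LoVo vector 2 and 3.60 in the array labelled LoVo LIN28B 2. A true difference would therefore need vector cells with the LIN28B signal and LIN28B cells without it. An exchange needs neither, but 1 array per label does not settle the question.

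The LIN28B-related difference shared by both lines was very large, with 69 genes over 3 log2. Admixed hepatocyte-like RNA is left open as a source of the higher liver-type transcripts. It could lower genes of the cultured cells only by dilution, which would act on all of them alike. Yet 180 genes lay lower by over 1 log2, while the colonocyte and goblet lists had 7 and 6 members higher and 0 lower. These values, weighed after the result was seen, argue against admixture as the source of the lower genes. Of 18 abundant hepatocyte transcripts, 14 were higher without the second LoVo pair, such as TTR, APOA2 and APOB. ALB rose by only 1.16, to at most 5.10, and TF differed by 0.20 without passing the test. These 2 genes cannot exclude admixture for the higher transcripts, since both lay below the dim cut of 5.29 in every array and were chosen after the result was seen. Cells of different chromosome content on the arrays of high and low LIN28B may be part of the difference, since the covariance of window medians between the DLD-1 pair and the first LoVo pair was 8.75 (in units of 1000 times log2 squared) and none of 1000 shuffles of gene positions exceeded 2.53; gene density is argued against as its source, as 8.61 remained with density regressed out. Neighbouring genes that respond together would raise this covariance too, and no reference profile of either line was used. A response to LIN28B is left open: the 1848 genes called with the same sign in both lines do not test it, because the fit can hardly call a gene with opposite signs.

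With all 6 arrays as labelled, the fit over both lines called 0 genes, and so did 8 of the 9 other splits of the arrays into 3 and 3. The highest other split called 3575 genes and is the one with the arrays of the second LoVo pair exchanged, which points to a structure of the samples; it was counted only as one of all possible splits. Since the labels gave 0 genes, 10 of 10 splits reach that count by construction, and 10 splits are too few for a share under 0.05.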

How the results depend on the processing

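The fits without the second LoVo pair, their tests of lists and the crossed block were chosen only after the result was seen; the other alternatives were planned. The counts of 0 in LoVo, over both lines and for the interaction stayed at 0 under each scaling, filter, probe set and variance alternative, and under each array left out where the fit could be made; with a lone array in a group, that array is assumed to vary like the others. Named genes kept their result in 1439 cases, with 29 reversals, 12 calls gained and 8 lost. Counts and correlations kept theirs in 142 cases, moved in 45 and reversed in 2, a correlation being taken as moved beyond 0.05. The causes of the changes were not tested.

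The second LoVo pair decided the result. Without it, 1067 genes were higher and 781 lower over both lines, 2372 higher and 990 lower between lines, and 9 lists higher and 0 lower over both lines in place of 5 and 2. Of the 1848 genes, 1809 were also called with quantile normalization, 1793 with median centring, 1764 with the mean of a gene's probe sets, 1736 with trend and robust options and 1581 with the filter on dim genes, which tests fewer genes. In LoVo it turned the signs of LIN28B (4.01 without it, as values with no test), PROM1 (4.56), LGR5 (2.82), IGF2BP1 (3.19), MYC (−0.23) and CDH1 (−0.0196). The correlation of −0.04 between lines became 0.75 with the first LoVo pair alone, −0.76 with the second alone, 0.14 for the array labelled LIN28B 1 against vector 2 and −0.21 for LIN28B 2 against vector 1.

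With each array left out in turn, lists in LoVo ranged from 0 to 6 higher and from 0 to 4 lower, and over both lines from 2 to 8 higher and from 0 to 3 lower. Between lines, the count of higher genes ranged from 0 to 1, and DDIT4 from 3.54 to 3.88 with its call lost in 5 of the 6 fits. In LoVo the ranges were −2.32 to 1.90 for LIN28B, −2.71 to 2.61 for PROM1, −1.62 to 1.39 for LGR5, −1.72 to 1.70 for IGF2BP1, −0.0341 to 0.53 for IGF2BP3, −0.17 to 0.39 for MYC and −0.0099 to 0.32 for CDH1. Over both lines they were −0.21 to 2.76 for LIN28B, −0.0480 to 3.30 for PROM1, −0.12 to 1.93 for LGR5, −0.0103 to 2.38 for IGF2BP1 and −0.25 to 0.11 for MYC. There IGF2BP3 ranged from 0.23 to 0.56 and CDH1 from 0.14 to 0.33.

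An estimated inter-gene correlation left 0 lists higher and 0 lower in LoVo, over both lines and without the second LoVo pair. With 1 to 3 residual degrees of freedom, that version of camera could hardly pass any list. In LoVo, median centring and quantile normalization each gave 2 lists lower in place of 1, and the filter on dim genes gave 1 higher and 2 lower; median centring turned IGF2BP1 to 0.0050. Between lines, 9 genes were higher and 4 lower with trend and robust options, 48 and 19 with every probe set on its own, and 6 and 3 with median centring, in place of 1 and 0. At a size of 0.5 log2 in DLD-1, 1372 genes were higher and 1643 lower.

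With the replicate block, 0 genes were called in LoVo and 0 over both lines, and no list's count changed. Deviations of same-numbered LoVo arrays correlated at −0.82; the crossed pairing as a block called 0 genes higher and 0 lower. Not run were the pseudocounts, since the values are log2, and the interaction without either DLD-1 array or without the second LoVo pair, which leaves an arm or the residual degrees of freedom empty. Arrays were scaled alike: the largest shift of an array's median gene was 0.05 log2. Signal near background was not measured here, so low values such as 3.60 for LIN28B have no floor to be set against.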

Other observations

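The tests in this part were chosen only after the result was seen, though the gene lists of the line comparison were fixed beforehand.

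Without the second LoVo pair, the same 11 lists passed camera between the lines as with all 6 arrays, with the called members below. Proliferation genes had 21 of 30 members lower and 0 higher in LoVo (25 and 0 adjusted over the list alone), with a median of −0.73, replication histones 14 of 55 lower and 0 higher (16 and 0), and cholesterol synthesis genes 6 of 17 lower and 1 higher (12 and 1). Stress genes of the unfolded protein and amino acid responses had 14 of 23 members higher and 2 lower (17 and 2), with a median of 1.07, and hypoxia genes 8 of 18 higher and 0 lower (10 and 0). Epithelial adhesion had 10 of 21 higher and 0 lower (10 and 0), invasion genes 11 of 24 higher and 0 lower (12 and 1), interferon response 8 of 28 higher and 0 lower (10 and 0), insulin and IGF signalling 7 of 21 higher and 0 lower (8 and 0), and Wnt targets 9 of 23 higher and 1 lower (9 and 2). Oxidative phosphorylation had 11 of 78 lower and 0 higher (10 and 0). For these lists limma's camera gave adjusted p values from 1.9e-11 to 0.0146 with the preset correlation, and adjusted p = 0.624 with an estimated one. The latter version had 1 residual degree of freedom and could hardly pass any list. The pairs in brackets are the counts adjusted over the list alone, in the order of the counts before them.

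Secreted liver-type proteins were a further group in the arrays labelled LIN28B of the DLD-1 pair and the first LoVo pair. Of 18 abundant hepatocyte transcripts, a list chosen after its values were seen, 14 were higher and 0 lower, with a median of 2.50 in DLD-1, 1.83 in the first LoVo pair and −1.78 in the second as labelled. APOA2 differed by 4.30 ± 0.18 and TTR by 4.54 ± 0.18, and the fibrinogen chain FGG by 3.41 ± 0.16, whereas haptoglobin (HP) at 0.08 ± 0.14 and AMBP at −0.21 ± 0.15 did not pass.

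LIN28A, the paralogue of LIN28B, was represented by 2 probe sets, which differed by 0.58 and 0.00 in DLD-1, by 0.35 and 0.01 in the first LoVo pair and by −0.42 and −0.06 in the second as labelled. The probe set given first read only 3.42 to 4.10 log2, below the lower quartile of each array. The other, used in the tests, read 4.68 to 5.15, so the values do not show that LIN28A followed LIN28B.

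Along the chromosomes, the SD of the window medians was 0.11 log2 in the DLD-1 pair, where the highest of 1000 shuffles of gene positions gave 0.07, and 0.11 in the first LoVo pair, where it gave 0.07. Between the lines' vector arrays it was 0.09, which 114 of 1000 shuffles reached, and between their LIN28B arrays of the first pair it was 0.11, above the highest shuffle of 0.10. The covariance of the line differences in vector and LIN28B arrays was 6.71, in units of 1000 times log2 squared, against a highest shuffle of 6.69.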
